A study of Mus musculus with 6 samples.

How the data were processed

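Gene expression was measured by sequencing of total RNA from inguinal white adipose tissue of mice fed a high-fat diet, in 4 Steap4f/f and 2 Steap4AKO libraries. Per the labels' protocols, RNA was extracted with a kit for lipid-rich tissue and libraries were prepared by a sequencing company; the strandedness of the library preparation is not given in the sources used here. Per the submitters' processing notes, the tools were STAR 2.7.0e, RSEM 1.3.3, R 4.2.0 and DESeq2 1.12.4, and the builds GRCm38 and mm10. These notes give no role or order of the tools, and the gene annotation is not given in the sources used here.

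The deposited table held 1 column per library and 15176 genes, and its unit was a signal, gene counts normalized by the authors with DESeq2, per the name of the table. Its lowest row reached 11.8 in its highest library, so that each gene in the table was at least that high in 1 library. The values were not whole multiples of 1 read: among low values, 34.3 to 58.3% lay within 0.1 of a whole read at the best step of each column. Whole reads were therefore not recovered, no count test was run, and depth is known only as an estimate, from 11600000 to 19500000 reads, from the value of 1 read (0.99 to 1.43). The shallowest library, Steap4AKO replicate 2, gives the least precise values for low genes, and no counting intervals were computed. Counts assigned by RSEM divide reads between near-identical genes, so that genes with copies are uncertain. Gene symbols came from GENCODE M21 on GRCm38 by Ensembl identifier, which matched 15125 genes; 51 had no symbol. Coordinates are those of GRCm38.

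Differences were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity-dependent variance trend and a 2-group design over all 6 libraries, for 15006 genes with a mean value of at least 10, which removed 170 genes. Adjusted p-values are Benjamini-Hochberg over these genes, with a threshold of 0.05, and all tests were two-sided. Log2 differences are Steap4AKO minus Steap4f/f on the log2(value + 1) scale, which understates changes of low genes, and folds are ratios of group means of the deposited values. The design stated at submission gave no batch, litter or sex, so no covariate was fitted. Gene lists, 31 of pathways and 15 of cell types, were fixed before the data were examined, as were the tests and most of the other settings. Each list with at least 3 measured members was tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and the union of respiratory chain lists, and with camera at an estimated correlation and fry beside it. Camera asks whether a list differs from other genes.

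Genes named in the text followed a rule fixed before the data were examined: Steap4; the 12 called genes with the largest change in each direction, or all if fewer, with a mean of at least 50 in the higher group, no overlap between groups and a named symbol; the 4 members with the smallest p in the direction of each called list, so that these examples do not show members that went the other way; called members of other pathway lists; and Ucp1, Cidea, Ppargc1a, Dio2, Adipoq, Lep, Pparg, Tfrc, Fth1 and Adgre1. Of the genes this gave, 130 are reported and the rest are not reported here, and other genes are said to be chosen after their values were seen. A muscle index per library was the mean over 16 skeletal muscle markers of the value divided by the Steap4f/f mean. Lists of subcutaneous depot, visceral and mesothelial, and epididymis genes were written after some of these genes had been seen, with 8, 12 and 12 members in the table; 27 epididymis genes had been listed, and the other 15 were not analysed here.

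The fitting was tested on simulated data for this comparison, with 14786 to 14831 genes and 200 changed genes in each of 5 runs. It recovered 25% of genes changed 2-fold and 75.6% of genes changed 4-fold, with 6.4 false calls per run, found a list shifted by -0.8 in 5 of 5 runs and called 0 of 10 unshifted lists. Lists were scored there at an unadjusted camera p under 0.05. The simulated genes varied independently of each other, so that these runs do not test lists with correlated members. Changed genes were drawn from means of at least 50 and the shifted list from means of at least 200. The SDs of the most variable genes were capped, and all simulated libraries varied alike. The recovery and false call rates therefore need not hold for low genes or for real libraries of which 1 stood apart. Alternatives were other pseudocounts, filters on low values, scalings, array weights, a robust variance prior, other thresholds, other list tests and each library left out. The muscle index as a covariate and sums of mitochondrial genes with their chromosome 1 copies were added after seeing the data. edgeR and DESeq2 tests, planned only for whole reads, were not run. Alignments of copies and figures were made with Python 3.11.15, Biopython and matplotlib.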

Results

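RNA was sequenced from inguinal white adipose tissue (iWAT), a subcutaneous fat pad, of mice fed a high-fat diet (HFD). The 6 libraries came from 2 genotypes: 4 from Steap4f/f mice, which carry the floxed Steap4 gene and served as controls (replicates 1, 2, 5 and 6), and 2 from Steap4AKO mice, in which Steap4 was deleted in adipocytes (replicates 2 and 3). The deposited table gave normalized values for 15176 genes, which summed to 19541419, 19532432, 18846321 and 20547925 in the Steap4f/f libraries and to 16573561 and 17979641 in the Steap4AKO libraries. The value of 1 read in the low range of each column put the depth at approximately 17500000, 19500000, 15900000 and 19400000 reads in Steap4f/f and at 11600000 and 18200000 in Steap4AKO, so that Steap4AKO replicate 2 was the shallowest library. The labels do not state that each library came from a separate mouse, and the p-values measure the spread between these samples. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had values of at least 311.5 in every library.

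The study asked what loss of Steap4 in adipocytes does to mitochondrial function in the adipose tissue of HFD-fed mice. Steap4 encodes a metalloreductase that reduces iron and copper. The gene (ENSMUSG00000012428) lies on chromosome 5, from 7960457 to 7982213 on the plus strand of GRCm38. Its normalized value was 10900 ± 4104 (SD, n = 4) in Steap4f/f and 8163 ± 211 (SD, n = 2) in Steap4AKO, a log2 difference of -0.35 (SE 0.29) that did not pass the test (limma, adjusted p = 0.544). Steap4f/f replicate 1 stood at 17018, while the other 3 Steap4f/f libraries lay between 8310 and 9417 and the Steap4AKO libraries stood at 8313 and 8014. Without Steap4f/f replicate 1 the log2 difference was -0.12 (adjusted p = 0.718). The genotype labels were therefore not checked by the level of this transcript in whole tissue, where cells other than adipocytes can express it and a deleted allele can still give a partial transcript.

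**Figure D1:**
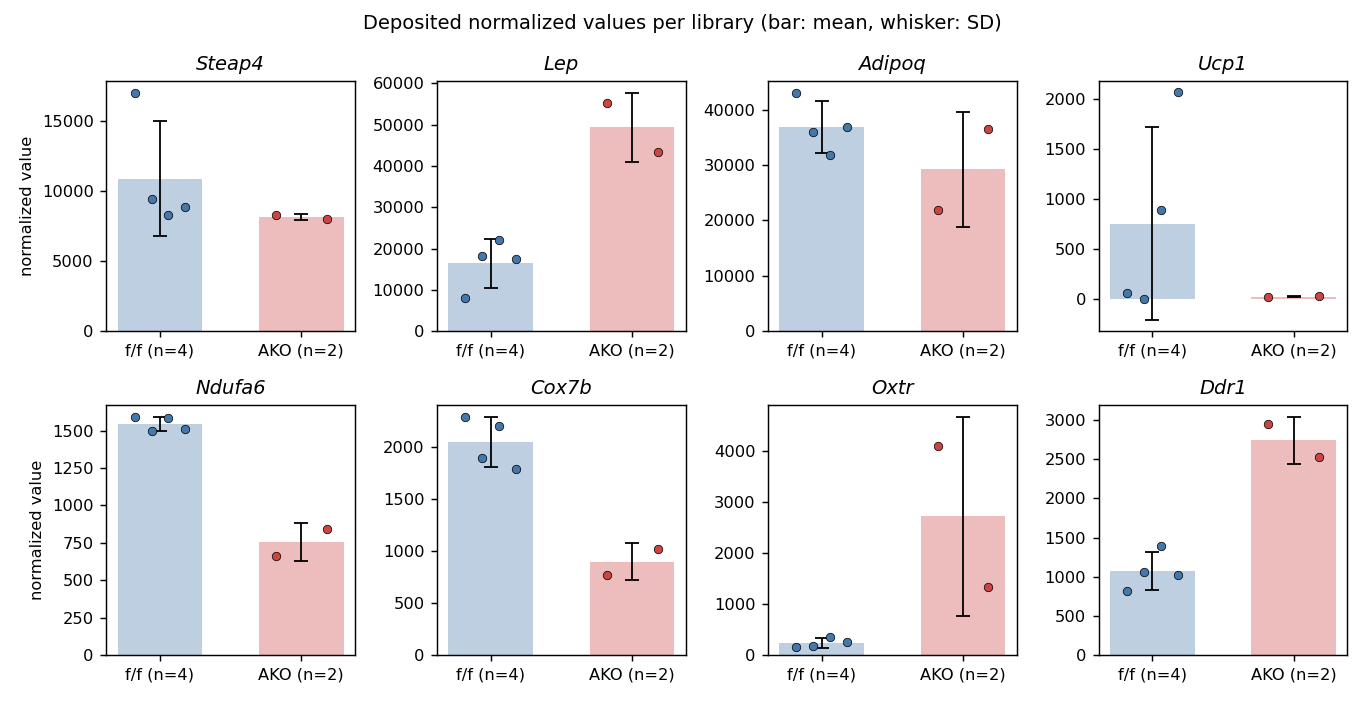
Deposited normalized values (y axis, linear) of 8 genes in the 4 Steap4f/f libraries (blue) and the 2 Steap4AKO libraries (red); bars are means, whiskers SDs and points libraries. Steap4 and Adipoq overlapped between the genotypes, Ucp1 ranged from 4.0 to 2069 within Steap4f/f, and Ndufa6, Cox7b, Lep, Oxtr and Ddr1 did not overlap.

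Subunits of the mitochondrial respiratory chain were lower in the 2 Steap4AKO libraries, of which replicate 2 stood apart from all others, with 1068 genes more than 2-fold above every other library and the subcutaneous depot gene Tbx15 at 1.4. Of 79 nuclear genes for complexes I to IV and ATP synthase, 78 had a lower mean log2 value in Steap4AKO and 77 were lower in both Steap4AKO libraries than in every Steap4f/f library, where chance gives a share of 6.7% in this direction and 2162 of the 15006 genes tested (14.4%) were lower in this way. The median log2 difference was -0.79, and it was -0.98 in Steap4AKO replicate 2 and -0.62 in replicate 3, against -0.07 to 0.04 in the Steap4f/f libraries. Ndufa6, an accessory subunit of complex I (chromosome 15, 82350140 to 82354322), was 2.05-fold lower, with 1546 ± 47.6 (SD, n = 4) in Steap4f/f and 754.5 ± 128.4 (SD, n = 2) in Steap4AKO. Cox7b, a subunit of complex IV (chromosome X, 106015700 to 106022450), was 2.29-fold lower, with 2043 ± 239.9 (SD, n = 4) against 893.7 ± 178.5 (SD, n = 2).

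The median log2 differences of complexes I, II, III, IV and ATP synthase were -0.80, -0.59, -0.89, -0.83 and -0.70. All 36 complex I genes were lower without overlap, and 3 of them passed the test over all genes, Ndufa6, Ndufs4 (1.93-fold lower) and Ndufb11 (1.86-fold lower), while Ndufa13 had an adjusted p of 0.0527 in limma. In complex III, Uqcrq (2.09-fold lower) and Uqcrb (2.05-fold lower) were 2 of 9 members past the threshold, and Uqcrh and Uqcr10 had 1.70-fold and 1.80-fold lower means. In complex IV, Cox7b, Cox5a (2.08-fold lower) and Cox6a2 were 3 of 15 members past it, and Cox7c had a 1.92-fold lower mean. Cox6a2 is the isoform of heart and skeletal muscle and was 54.2-fold lower. In ATP synthase, Atp5j2 (1.98-fold lower) passed, and Atp5e, Atp5d and Atp5o had 1.86-fold, 1.74-fold and 1.72-fold lower means. None of the 4 complex II genes Sdhd, Sdhb, Sdhc and Sdha passed, with means 1.51-fold, 1.79-fold, 1.39-fold and 1.41-fold lower.

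In total 9 of the 79 respiratory chain genes passed the threshold over all genes, and 76 did when adjusted over the list alone. The list as a whole was lower than other genes by camera (adjusted p = 9.35e-36 with the preset correlation of 0.01), and the adjusted p was 0.345 with an estimated correlation. By fry, which asks whether the members move on balance in 1 direction, its adjusted p was 0.0238. Without Steap4AKO replicate 2 the median was -0.62 (camera adjusted p = 6.08e-29). The camera adjusted p-values of complexes I, II, III, IV and ATP synthase were 3.22e-23, 0.00867, 1.28e-08, 7.71e-11 and 4.07e-10, and with an estimated correlation these adjusted p-values were 0.345, 0.491, 0.345, 0.345 and 0.345. Without Steap4AKO replicate 2 complex II had a median of -0.33 and an adjusted p of 0.132, and without Steap4AKO replicate 3 its median was -0.94.

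**Figure D2:**
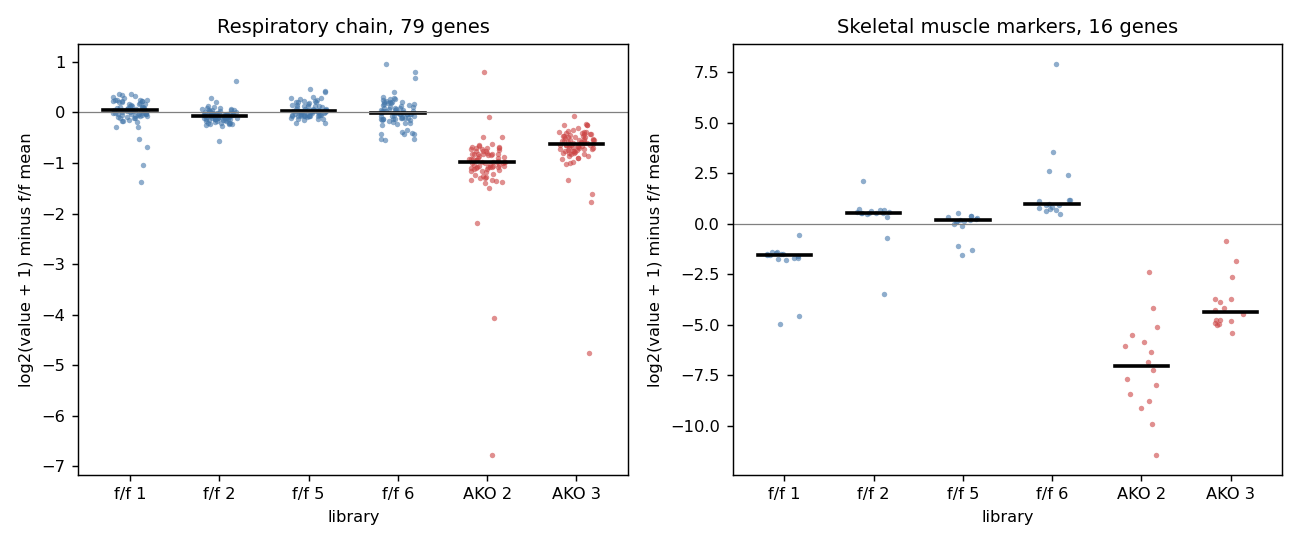
Left, log2(value + 1) of 79 respiratory chain genes minus their Steap4f/f mean, per library; right, the same for 16 skeletal muscle markers; each point is a gene and each black line the median over genes. The chain medians were -0.98 and -0.62 in Steap4AKO, and the muscle medians ranged from -1.56 to 0.95 in Steap4f/f and were -7.04 and -4.40 in Steap4AKO.

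Other mitochondrial genes were lower as well. The 13 messenger RNAs encoded by mitochondrial DNA had a median log2 difference of -0.90, which was -0.35 under quantile normalization (camera adjusted p = 0.00102). The camera adjusted p of this list was 2.57e-08, and the adjusted p was 0.388 with an estimated correlation. The means of mt-Atp8, mt-Nd4l and mt-Nd3 were 2.01-fold, 1.71-fold and 2.09-fold lower. Genes of the mitochondrial genome made up 8.6, 7.4, 6.4 and 9.0% of the deposited values in Steap4f/f and 4.2 and 5.5% in Steap4AKO. These percentages leave out values assigned to near-identical copies on chromosome 1 and are therefore too low. For mt-Co2, mt-Atp6 and mt-Co3 the copies held 88.0 to 94.4% of the summed values in Steap4f/f and 85.3 to 95.2% in Steap4AKO. mt-Co2, at 3.14-fold lower, was the 1 member past the threshold, but it is identical over 681 bases to the chromosome 1 copy Gm28661, so that reads of these 2 cannot be told apart, and their sum was lower by a log2 difference of -0.99. The 78 mitochondrial ribosomal protein genes had a median of -0.43, with 76 of them lower, none past the threshold over all genes and 10 when adjusted over the list alone. Mrpl12, Mrpl51, Mrps21 and Mrps31 had means 1.74-fold, 1.61-fold, 1.52-fold and 1.6-fold lower. All 21 genes of the tricarboxylic acid cycle list had lower means (median -0.67, 17 past the threshold when adjusted over the list alone), among them Fh1, Mdh2, Idh3b and Pdhb with means 1.95-fold, 1.71-fold, 1.83-fold and 1.78-fold lower. Cytochrome c (Cycs) and Chchd10, named here after their values were seen, passed the threshold at 2.01-fold and 3.82-fold lower.

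Fuel oxidation followed the same direction. In fatty acid oxidation 24 of 26 genes had lower values (median -0.63, 15 lower and 1 higher past the threshold when adjusted over the list alone), led by Etfb, Acadvl, Slc25a20 and Decr1, with means 1.96-fold, 1.97-fold, 1.72-fold and 1.55-fold lower. All 19 genes of branched-chain amino acid catabolism had lower values (median -0.57), none past the threshold even when adjusted over the list alone, and Bcat2, Mccc1 and Bckdha had means 1.73-fold, 1.65-fold and 1.55-fold lower. The list of mitochondrial biogenesis and dynamics had a smaller median of -0.19, with Mief2 1.83-fold lower past the threshold when adjusted over the list alone and Phb2, Phb and Twnk at 1.46-fold, 1.26-fold and 1.33-fold lower means. The mitophagy and quality control list had a median of -0.26, with Hspd1, Hspe1, Map1lc3a and Lonp1 at 1.44-fold, 1.73-fold, 1.41-fold and 1.33-fold lower means. The camera adjusted p-values of these 7 lists, from mitochondrial DNA to quality control, were 2.57e-08, 1.87e-16, 1.79e-10, 1.74e-07, 6.08e-06, 0.0238 and 0.0135, and the adjusted p-values with an estimated correlation were 0.388, 0.345, 0.491, 0.491, 0.491, 0.491 and 0.491. In Steap4AKO replicate 3 alone the medians were -0.65, -0.32, -0.40, -0.24, -0.12, -0.11 and -0.08, and without Steap4AKO replicate 2 the last 3 lists had adjusted p-values of 0.203, 0.455 and 0.415. The list of biogenesis and dynamics had an adjusted p of 0.0593 without Steap4f/f replicate 2 and of 0.0585 without Steap4f/f replicate 6. Without Steap4AKO replicate 3 the medians of the tricarboxylic acid cycle, branched-chain amino acid and quality control lists were -1.03, -0.96 and -0.46.

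Across the transcriptome 71 of 15006 genes passed an adjusted p of 0.05 in limma, 6 higher and 65 lower in Steap4AKO, and 2717 had an unadjusted p under 0.05. Among the higher genes were Oxtr, Fmn1, Slc6a6, Adcyap1r1 and Ddr1. Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112489943), was 11.6-fold higher, with 234.8 ± 91.5 (SD, n = 4) in Steap4f/f and 4093 and 1331 in the Steap4AKO libraries. Slc6a6, the taurine transporter, was 2.08-fold higher, Ddr1, a collagen receptor kinase, 2.55-fold, Adcyap1r1, a receptor of the neuropeptide PACAP, 2.33-fold and Fmn1, a formin, 5.08-fold.

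Skeletal muscle markers were lower in Steap4AKO. Among the largest decreases, Mybpc2, Mylk2, Trim54, Dhrs7c, Lbx1, Cacng6, Tmem233, Klhl31, Actn3 and Pvalb passed the threshold at 65.9-fold to 282-fold lower, and Vgll2, a cofactor expressed in skeletal muscle, had values of 64.0, 153.7, 20.5 and 129.1 in Steap4f/f and was listed at 0 in both Steap4AKO libraries. The 282-fold of Lbx1 divides by Steap4AKO values of 0 and 1.0, near that of 1 read, and its log2 difference was -6.28. Cacng6, Trim54 and Dhrs7c had 0.7, 0.7 and 0 in Steap4AKO replicate 2, so that their folds are imprecise too. Mybpc2, a myosin-binding protein of fast muscle fibres (chromosome 7, 44501699 to 44524656), had 4524, 16974, 12952 and 22289 in Steap4f/f and 22.1 and 380.8 in Steap4AKO. Of 16 skeletal muscle markers fixed beforehand, 6 were among the 71 genes past the threshold and 14 passed when adjusted over the list alone. Among these were Ckm, muscle creatine kinase, at 55.9-fold lower and Tnnc2 at 39.7-fold lower (median -5.52, camera adjusted p = 5.93e-13). With an estimated correlation the adjusted p of this list was 0.407. The mean level of these markers relative to the Steap4f/f mean was 24.5, 106, 74.9 and 195% in the Steap4f/f libraries and 0.809 and 5.18% in the Steap4AKO libraries, so that it differed by 8.0-fold within Steap4f/f as well. This mean weighs each marker alike and so depends on fibre type as well as on the amount of muscle. The marker Myh7, a slow myosin, had 7619.5 in Steap4f/f replicate 6 and at most 44.5 in the other Steap4f/f libraries, while Ckm ranged from 15911.9 to 81342.5. With the mean level of the 16 markers as a linear covariate, added after seeing the data, 10 of the 28 lists past the camera threshold no longer passed. The adjusted p-values were 0.217 for futile cycles, 0.08 for complex II, 0.383 for mitochondrial biogenesis, 0.0869 for mitochondrial quality control and 0.383 for cholesterol. They were 0.283 for lipolysis, 0.228 for cytokines, 0.166 for adipocytes, 0.0674 for macrophages and 0.283 for T and NK cells. The linear covariate correlated with genotype at -0.67, which widens the error of the genotype difference. A lost call therefore need not mean a smaller change. With this covariate 2 lists were gained, the antioxidant response (median -0.30, adjusted p = 0.0317) and B cells (median 2.55, adjusted p = 0.0488).

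Muscle genes were among the members of other lists as well. The futile cycle list, with 8 of 15 members lower and 7 higher, had a median of -0.40 and a camera adjusted p of 0.043 (adjusted p = 0.396 with an estimated correlation), and its lowest members were the muscle genes Ryr1 (35.4-fold lower, past the threshold), Ckmt2 and Atp2a1 (means 45.1-fold and 58.7-fold lower), followed by Slc25a4 (mean 2.86-fold lower). Its camera adjusted p was 0.0588, 0.062 and 0.113 without Steap4f/f replicate 2, 5 or 6. Its median was -0.21 without Steap4f/f replicate 1 and -0.26 without Steap4AKO replicate 2, while in Steap4AKO replicate 2 alone it was -0.49. In the cytosolic ribosome list, which had a median of -0.25 and an adjusted p of 1.79e-08 (0.491 as the adjusted p with an estimated correlation), the member past the threshold was Rpl3l, a muscle paralog, at 34.5-fold lower, and Rplp2, Rpl39l and Rpl37 had means 1.67-fold, 5.01-fold and 1.81-fold lower. The ribosome median was -0.12 in Steap4AKO replicate 2, which had the lowest muscle markers, and -0.40 in replicate 3. It was -0.39 with the linear muscle covariate (adjusted p = 7.31e-13) and -0.14 under quantile normalization. The hypoxia and glycolysis list went both ways, with 16 of 21 members lower and 5 higher, and with 6 lower and 3 higher when adjusted over the list alone. It had a median of -0.27 and an adjusted p of 0.0154 (adjusted p = 0.372 with an estimated correlation), with the glycolytic genes Aldoa, Gapdh, Pkm and Gpi1 at means 3.44-fold, 2.62-fold, 2.43-fold and 1.84-fold lower. The 3 higher members, Hif1a, Hk1 and Adm, named here after their values were seen, had means 1.70-fold, 1.5-fold and 1.97-fold higher. In Steap4AKO replicate 3 the median of that list was -0.03, against -0.44 in replicate 2, and without Steap4AKO replicate 2 its adjusted p was 0.253.

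The number of genes past the threshold was not stable, and 70 of the 71 had adjusted p-values between 0.0466 and 0.0492. Leaving out Steap4AKO replicate 2, or any 1 of Steap4f/f replicates 2, 5 and 6, left 1 gene, while 238 passed without Steap4f/f replicate 1 and 821 (455 higher and 366 lower) without Steap4AKO replicate 3. The gene that remained was Gm29216, a pseudogene copy of mt-Co1 on chromosome 1 (24615706 to 24616197), named here after its values were seen, with values of 17436, 6209, 6465 and 7703 in Steap4f/f and listed at 0 in both Steap4AKO libraries (adjusted p = 1.86e-05).

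Thermogenic and beige adipocyte genes did not pass as a list. Of 28 measured members 18 had lower and 10 higher values in Steap4AKO, with a median log2 difference of -0.51 (camera adjusted p = 0.088), no member past the threshold over all genes and 3 when adjusted over the list alone. Ucp1, the uncoupling protein of thermogenic fat, had 58.0, 4.0, 890.8 and 2069 in Steap4f/f and 17.2 and 26.9 in Steap4AKO (log2 difference -2.76, SE 2.14, adjusted p = 0.521), so that its spread within Steap4f/f covered the Steap4AKO values. Cidea had a 3.64-fold lower mean (adjusted p = 0.207), Ppargc1a, a coactivator of mitochondrial biogenesis, 2.04-fold lower (adjusted p = 0.351) and Dio2, the thyroid hormone deiodinase, 2.21-fold lower (adjusted p = 0.464), each with overlapping libraries. Without Steap4f/f replicate 1 the list had a median of -0.40 and an adjusted p of 0.0312, and without Steap4f/f replicate 2 these were -0.55 and 0.0276.

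Adipocyte hormones and lipid genes went in different directions. Lep, which encodes leptin (chromosome 6, 29060220 to 29073877), had 16470 ± 5947 (SD, n = 4) in Steap4f/f and 49320 ± 8321 (SD, n = 2) in Steap4AKO, a 2.99-fold higher mean without overlap that did not pass the threshold (adjusted p = 0.0988). Adipoq (adiponectin) had 36900 ± 4637 (SD, n = 4) against 29220 ± 10410 (SD, n = 2) (adjusted p = 0.475), and Pparg, the master regulator of adipocyte differentiation, had 4531 ± 730.1 against 3928 ± 2023 (adjusted p = 0.625). The list of adipocyte differentiation and adipokine genes had a median of -0.35, a mean of -0.01 and an adjusted p of 0.338. The 10 adipocyte markers had a median of -0.34 (camera adjusted p = 0.0432, adjusted p = 0.495 with an estimated correlation), which was -0.76 in Steap4AKO replicate 2 and 0.02 in replicate 3. The adjusted p of these markers was 0.0928, 0.0588, 0.054 and 0.0737 without Steap4f/f replicates 1, 2, 5 and 6 in turn and 0.981 without Steap4AKO replicate 2. The adipokine list passed without Steap4AKO replicate 3 (-0.57, adjusted p = 0.0139). Cfd (adipsin), Pck1 and Acvr1c had means 3.35-fold, 2.30-fold and 1.28-fold lower, none past the threshold, and Fabp4 had a log2 difference of -0.68 that became 0.15 under quantile normalization.

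Among lipid pathways, de novo lipogenesis and triglyceride synthesis had a median of -0.47 with 19 of 25 genes lower (camera adjusted p = 0.00955), and lipolysis and lipid droplet genes had a median of -0.28 with 15 of 19 lower (adjusted p = 0.0376). The adjusted p was 0.491 for both with an estimated correlation. Elovl6, Tkt, Acaca and Pnpla3 had means 1.85-fold, 1.90-fold, 2.01-fold and 1.83-fold lower, and Adrb3 (the adipocyte beta-3 adrenergic receptor), Plin5 and Hcar2 had means 2.09-fold, 2.33-fold and 2.35-fold lower, none past the threshold over all genes. In Steap4AKO replicate 3 the medians of these 2 lists were -0.06 and 0.05, and without Steap4AKO replicate 2 their adjusted p-values were 0.382 and 0.981, while without Steap4AKO replicate 3 the medians were -0.72 and -0.67. The lipogenesis median was -0.31 without Steap4f/f replicate 1. The adjusted p of the lipolysis list was 0.0593, 0.087 and 0.131 without Steap4f/f replicate 2, 5 or 6. With no filter on low values this list had 20 members, a median of -0.27 and a camera adjusted p of 0.0642. Cholesterol synthesis and uptake genes were higher, with a median of 0.39, 20 of 21 genes higher and an adjusted p of 0.00867 (adjusted p = 0.491 with an estimated correlation). Stard4, Sc5d and Dhcr7 had means 1.83-fold, 1.5-fold and 1.88-fold higher, none past the threshold, and the list had a median of 0.25 and an adjusted p of 0.0457 without Steap4AKO replicate 2. The call was lost without Steap4f/f replicate 6, with a median of 0.26 and an adjusted p of 0.0648. It was also lost with the linear muscle covariate, with a median of 0.24 and an adjusted p of 0.383.

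Immune, smooth muscle, epithelial and cell cycle lists had higher medians over the 2 Steap4AKO libraries, which were larger in replicate 2 than in replicate 3, where the macrophage and epithelial medians lay below 0. Replicate 2 was also the library with the epididymal genes Akr1b7 at 38528 and Crisp1 at 8127 and with Tbx15 at 1.4. Macrophage markers had a median of 0.61 and lipid associated macrophage markers of 1.00, which were 1.39 and 1.90 in Steap4AKO replicate 2 and -0.07 and 0.06 in replicate 3. Adgre1, the macrophage marker F4/80, had 248.8 ± 90.3 (SD, n = 4) in Steap4f/f and 1750 and 291.8 in Steap4AKO, and Mpeg1, Csf1r and Lyz2 had 4690, 4343 and 11951 in Steap4AKO replicate 2 against 871.6, 1408 and 3589 in replicate 3. Itgax (1677 and 222.5), Mmp12 (4361 and 355.3), Lipa (4172 and 1440) and Atp6v0d2 (1155 and 54.5) showed the same order of the Steap4AKO libraries. T and NK cell markers had a median of 1.15 (1.59 and 0.69 in Steap4AKO replicates 2 and 3), with Il7r, Trac, Cd2 and Nkg7 at means 11.7-fold, 3.08-fold, 3.14-fold and 2.36-fold higher, and smooth muscle and pericyte markers a median of 0.89 (1.44 and 0.35), with Notch3, Kcnj8, Rgs5 and Myh11 at means 1.53-fold, 1.75-fold, 1.64-fold and 7.76-fold higher. Inflammatory cytokines and chemokines had a median of 0.78 (1.21 and 0.33), with Saa3, Cxcl10 and Il1rn at means 7.68-fold, 2.03-fold and 8.61-fold higher, and cell cycle genes a median of 0.65 (1.14 and 0.12), with Cenpf, Birc5, Ccna2 and Mcm6 at means 4.2-fold, 3.15-fold, 3.06-fold and 1.78-fold higher. In Steap4AKO replicates 2 and 3, Il7r had 545.6 and 38.6, Myh11 15119.8 and 1381.5, Il1rn 338.1 and 41, and Ccna2 374.7 and 97.1. The highest Steap4f/f values of these genes were 35.7, 1357.1, 43.4 and 92.2, near those in replicate 3. Notch3, Rgs5, Cxcl10 and Cenpf were instead higher in replicate 3 than in replicate 2.

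The epithelial markers Epcam (412.0 and 0.0), Krt8 (760.6 and 6.0), Cdh1 (334.5 and 32.2) and Elf5 (76.7 and 10.6) again differed between Steap4AKO replicates 2 and 3, and the median of their list was 3.26 (5.96 and -0.17). Steap4AKO replicate 2 also held the mesothelial gene Upk3b at 781. Peripheral nerve and Schwann cell markers had a median of -1.48, which was -2.51 and -0.38 in Steap4AKO replicates 2 and 3, and Sox10 and Prx had means 2.93-fold and 2.58-fold lower. The camera adjusted p-values were 0.0135 for macrophages, 0.00589 for lipid associated macrophages, 0.00894 for T and NK cells, 0.0147 for smooth muscle, 0.0187 for cytokines, 0.00037 for the cell cycle, 0.0121 for epithelium and 0.0122 for nerve, and no single gene of these lists passed the threshold over all genes. With an estimated correlation the adjusted p was 0.544 for macrophages and 0.491 for the other 7 lists, and without Steap4AKO replicate 2 the adjusted p-values were 0.455, 0.629, 0.14, 0.296, 0.395 and 0.478 in that order up to the cell cycle and 0.296 for nerve. The epithelial list had too few members for a test without Steap4AKO replicate 2. With a filter on a mean of at least 50 its adjusted p was 0.0593 over 5 members, and the T and NK list had too few members for a test.

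**Figure D3:**
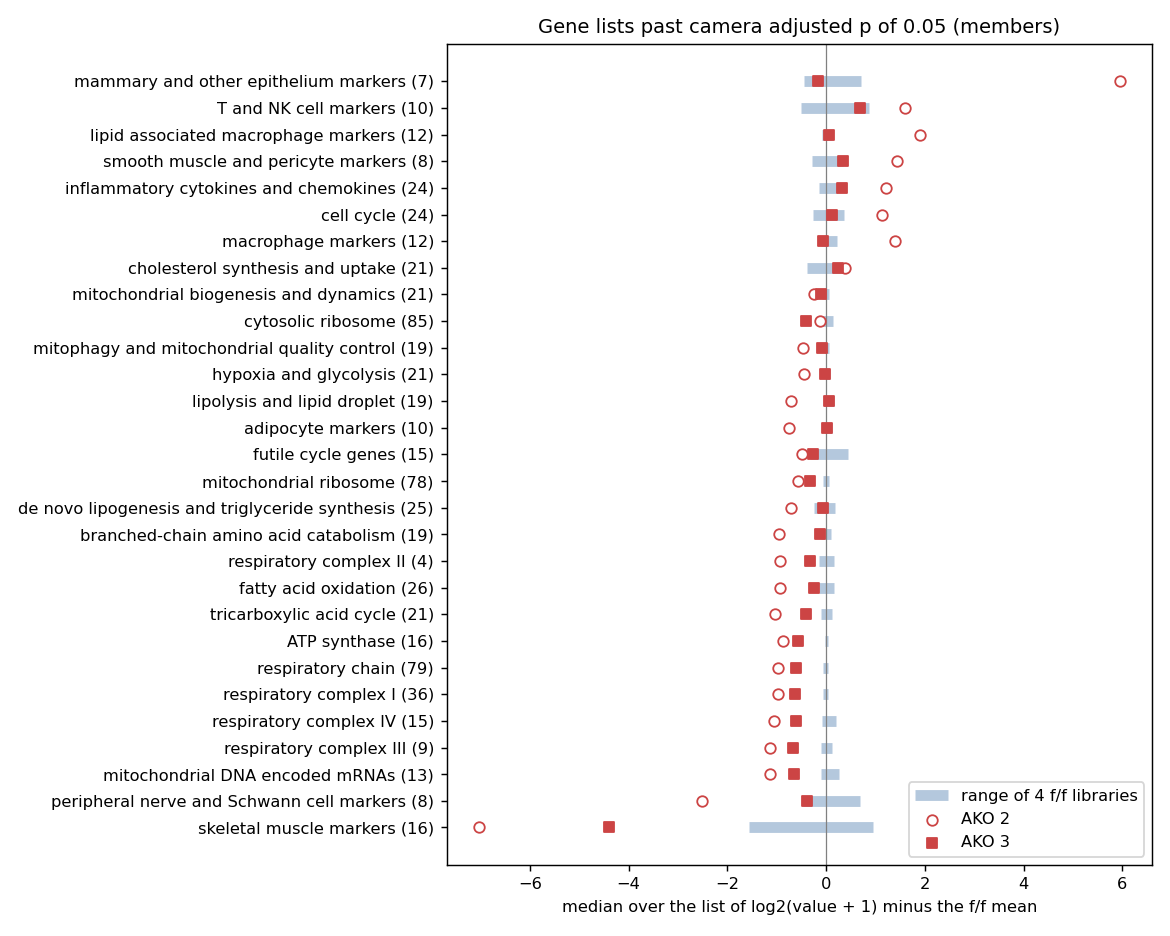
Median over each gene list of log2(value + 1) minus the Steap4f/f mean (x axis) for the lists past the camera threshold, with members in parentheses; blue bars span the 4 Steap4f/f libraries, open circles are Steap4AKO replicate 2 and filled squares replicate 3. Respiratory chain lists lay below the Steap4f/f range in both Steap4AKO libraries, while macrophage, epithelial and adipocyte markers lay near 0 in replicate 3.

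Lists for metal handling did not pass. Iron handling genes had a median of 0.12 over 32 members (adjusted p = 0.612) and copper handling genes a median of -0.11 and a mean of 0.06 over 20 (adjusted p = 0.278), and no member of either passed even when adjusted over the list alone. Tfrc, the transferrin receptor, had 470.0 ± 205.7 (SD, n = 4) against 489.9 ± 179.1 (SD, n = 2), and Fth1, ferritin heavy chain, had 31760 ± 2299 (SD, n = 4) against 27400 ± 369.1 (SD, n = 2) (adjusted p = 0.900 and 0.567, limma). The related genes Steap2 and Steap3, named here for their kinship to Steap4, had means 1.32-fold and 1.14-fold higher (adjusted p = 0.664 and 0.571).

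The remaining lists also did not pass. Their medians and camera adjusted p-values were -0.17 and 0.126 for the antioxidant response (0.0317 with the linear muscle covariate), -0.06 (mean 0.09) and 0.92 for the integrated stress and unfolded protein response, 0.10 (mean -0.05) and 0.942 for insulin signalling, 0.01 (mean -0.02) and 0.92 for the interferon response, 0.13 and 0.55 for extracellular matrix, 0.34 and 0.236 for the circadian clock, and 0.37 and 0.157 for immediate early genes. Among cell types they were -0.13 and 0.154 for stromal and progenitor cells, 0.02 and 0.437 for endothelium, 1.51 and 0.0574 for B cells, 0.85 and 0.206 for plasma cells, -1.31 and 0.088 for granulocytes and mast cells, -0.13 (mean 0.49) and 0.949 for skin, and 0.67 and 0.201 for red blood cells. In total 28 of 46 lists passed camera with the preset correlation, 8 higher and 20 lower, 0 passed with an estimated correlation, 6 passed by fry and 15 passed camera without Steap4AKO replicate 2. Under quantile normalization 6 of the 28 no longer passed. The adjusted p-values were 0.0838 for futile cycles, 0.11 for mitochondrial quality control, 0.147 for lipogenesis, 0.33 for lipolysis, 0.07 for hypoxia and glycolysis and 0.494 for adipocyte markers. Some other lists passed with 1 library left out. The adjusted p was 0.0312 for immediate early genes without Steap4f/f replicate 1 (median 0.47). Without Steap4f/f replicate 5 it was 0.0291 for B cells (median 1.80) and 0.0176 for granulocytes (-1.56). Without Steap4AKO replicate 2 it was 2.34e-05 for the clock (0.92) and 0.0431 for granulocytes (-1.29), and without Steap4AKO replicate 3 it was 0.0184 for B cells (2.50) and 0.00977 for plasma cells (2.32). The interferon list passed in opposite directions, higher without Steap4AKO replicate 2 (median 0.20, adjusted p = 0.0174) and lower without Steap4AKO replicate 3 (median -0.33, adjusted p = 0.0328). With a filter on a mean of at least 50, the adjusted p was 0.0577 for both futile cycles and adipocyte markers, 0.018 for granulocytes (lower) and 0.0435 for red blood cells (higher). With a pseudocount of 5 the B cell list passed camera too (median 1.2, adjusted p = 0.0368).

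Steap4AKO replicate 2 stood apart from the other 5 libraries. It held 1068 genes at more than 2-fold above every other library, against 19 to 144 in the others, and its median correlation across genes with the other libraries was 0.84, against 0.93 to 0.95. The subcutaneous depot gene Tbx15 had a value of 1.4 there and of 316.1 to 1330 elsewhere, and Hoxc10 had 53.6 against 496.9 to 743.5. The epididymal genes Akr1b7 and Crisp1 had 38528 and 8127 there and at most 3.2 and 3.3 elsewhere, and the mesothelial gene Upk3b had 781 there and 167.1 in Steap4f/f replicate 6. Of 12 visceral depot and mesothelial genes, 8 were more than 4-fold above every other library there. Among these 8, Tcf21, Bnc1, Krt8 and Krt18 had at most 5.6, 9.5, 11.6 and 8.5 elsewhere. The lowest maximum of any gene in the table was 11.8, so that their part of the count was largely fixed by which genes the table holds. The genes named in this paragraph were chosen after their values were seen.

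**Figure D4:**
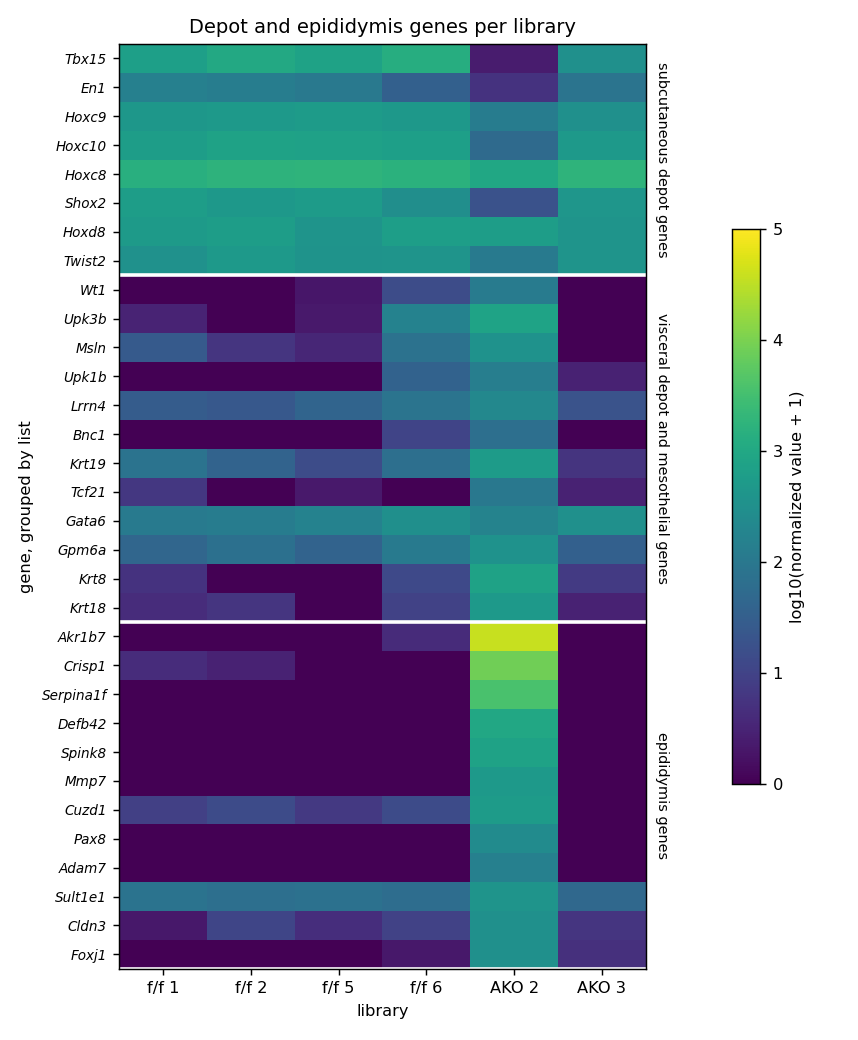
Normalized values (colour, log10(value + 1)) of subcutaneous depot genes, visceral depot and mesothelial genes and epididymis genes (rows) in the 6 libraries (columns). Steap4AKO replicate 2 had Tbx15 at 1.4 and Akr1b7 at 38528, and the other 5 libraries had Tbx15 at 316.1 or above and Akr1b7 at 3.2 or below.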

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

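Among 135 values examined in the 4 Steap4f/f libraries, 5 had a library far from the other 3, and chance alone gives about 5% of such groups. Steap4 was 17020 in Steap4f/f replicate 1, and 8310 to 9417 in the others. Cxcl10, a chemokine, was 47.2 in Steap4f/f replicate 6, and 72.1 to 75.2 in the others. Phb, a prohibitin of the inner mitochondrial membrane, was 3632 in Steap4f/f replicate 6, and 2773 to 2852 in the others. The epithelial genes Elf5 and Epcam were 1.4 and 2.4 in Steap4f/f replicate 5 and listed at 0 in the others, which are values near that of 1 read. The Steap4AKO group of 2 libraries was too small for this examination.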

How the results depend on the processing

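The muscle covariates and summed mitochondrial copies were chosen after seeing the data. The respiratory chain median (-0.79) stayed negative and past the camera threshold in every alternative run (-0.98 to -0.55) except that the adjusted p was 0.345 with an estimated correlation, and Steap4 stayed negative and short of the threshold in each (-1.37 to -0.12). Genes past the threshold numbered 71 (6 higher, 65 lower); 1 (0 higher, 1 lower) with a pseudocount of 0.5, a mean of at least 50, a robust variance prior or either muscle covariate; 123 (18 and 105) with a pseudocount of 5; 119 (115 lower) with array weights; 410 at adjusted p under 0.1; and from 1 to 821 (0 to 455 higher, 1 to 366 lower) with 1 library left out. Of the 71, 70 had adjusted p-values between 0.0466 and 0.0492; without Steap4AKO replicate 3, 58 of them were among the 821, and the cause of these differences was not tested. Lists past the threshold numbered 28; 0 with an estimated correlation, 6 by fry, 9 with the log2 muscle covariate, and 15 to 31 with 1 library left out. The thermogenic list, at -0.51, passed without Steap4f/f replicate 1 (-0.40) or replicate 2 (-0.55), and its range with 1 library left out was -0.55 to -0.26. The log2 muscle index correlates with genotype at -0.90, which leaves that fit little to separate; in it the thermogenic list reversed to 0.19 and 26 of 129 named genes reversed, none past the threshold: Ckmt2 0.16, Slc25a4 0.02, Sdhb 0.01, Sdhc 0.31, Sdha 0.14, Phb 0.11, Cidea 1.20, Plin5 0.56, Saa3 -0.03, Ccna2 -0.52, Mcm6 -0.66, Pck1 0.71, Myh11 0.00, Adgre1 -0.06, Csf1r -0.08, Lyz2 -0.73, Lipa -0.11, Atp6v0d2 -0.63, Nkg7 -1.12, Krt8 -0.64, Cdh1 -2.73, Epcam -3.52, Ucp1 0.87, Ppargc1a 1.14, Adipoq 0.01 and Pparg 0.16. Nkg7 reversed to -0.09 with the linear muscle covariate, and Fabp4 and Fth1 to 0.15 and 0.00 under quantile normalization. Tfrc reversed to -0.15 without Steap4f/f replicate 1 and to -0.26 without Steap4AKO replicate 2, where Lyz2 (-0.02), Cdh1 (-0.17) and Pparg (0.26) reversed too; with 1 library left out Tfrc, Lyz2 and Cdh1 ranged up to 0.50, 1.71 and 3.17 and Pparg down to -0.84. For these the cause was not tested. Without a Steap4AKO library, the lone sample is assumed to vary like the Steap4f/f libraries. No paired analysis was possible because the groups share only replicate number 2. The planned edgeR and DESeq2 tests were not run, because whole reads were not recovered. Depth limits low genes most in Steap4AKO replicate 2, at approximately 11600000 reads.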

Other observations

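The test of transcript length was written before its result was seen, and the other tests here were chosen only after the results were seen. Genes of the circadian clock differed between the 2 Steap4AKO libraries. In Steap4AKO replicate 3 the median of the clock list was 0.92, against -0.12 in replicate 2 and -0.14 to 0.09 in Steap4f/f, and the list passed camera without Steap4AKO replicate 2 (adjusted p = 2.34e-05). The activators Arntl and Npas2, which oppose Per1, Per3, Dbp and Hlf in phase, had 42.6 and 9.7 in Steap4AKO replicate 3, against 134.4 to 205.6 and 31.3 to 127.5 in Steap4f/f. The clock genes Per1 and Per3 and the output genes Dbp and Hlf had 4359, 2276, 4557 and 1044 there, each above the highest Steap4f/f values of 1913, 940.3, 2488 and 314.9. Times of tissue collection were not analysed here.

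Mest, Sfrp5 and Npr3 had higher values in both Steap4AKO libraries than in every Steap4f/f library, as had 2121 of the 15006 genes tested. Mest had 781 to 5903 in Steap4f/f and 23674 and 19200 in Steap4AKO, Sfrp5 had 560.3 to 2805 and 6327 and 5489, and Npr3 had 7609 to 15925 and 22007 and 23652. None passed the threshold over all genes in limma (unadjusted p = 0.00837, 0.0135 and 0.0194; adjusted p = 0.153, 0.179 and 0.198). Nnat, looked at with them, had 15719 to 33343 in Steap4f/f and 7064 and 35180 in Steap4AKO (adjusted p = 0.622). Steap4f/f replicate 1, lowest for Mest, Sfrp5, Npr3 and for Lep (8106), was also the library with the highest Steap4. Muscle fibre types differed within Steap4f/f: the slow myosin Myh7 had 7620 in replicate 6 and at most 44.5 in the others, while the fast myosin Myh4 had 42908 to 203597. These genes were chosen after their values were seen.

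Respiratory chain genes were lower in both Steap4AKO libraries. Skeletal muscle in the Steap4f/f samples is argued against as the whole cause: the slope of the chain genes on the muscle index within Steap4f/f gave a median predicted change of 0.05 (0.01 to 0.09 with each library left out), against the observed -0.79, although muscle isoforms such as Cox6a2 followed the markers. That slope rests on 4 libraries with an index of 24.5 to 195% and is extrapolated to 0.809 and 5.18%. The index also mixes fibre type with the amount of muscle. The range with each library left out is not a confidence interval, so that a part played by muscle is not excluded. A trend with transcript length is argued against too, since 0 of 10000 lists of other genes matched on length and level had a median as low. These lists centred on -0.1, with 95% of their medians between -0.19 and 0.00. Their genes were drawn independently, while the chain genes had an estimated correlation of 0.349. That band may therefore be too narrow for lists with correlated members. Fewer adipocytes may contribute in Steap4AKO replicate 2, where adipocyte markers had a median of -0.76 and the chain was at -0.98. In replicate 3 the marker median was 0.02, near the Steap4f/f mean, while the chain was at -0.62. The SDs over 10 markers, 0.66 and 1.23, exceeded these gaps, which the rule of this test counts as undecided. These SDs measure the spread between marker genes and not the error of a median. Each comparison also rests on 1 library, so that this stays open. The genotype, as a biological cause, and a difference in collection time stay open with 2 Steap4AKO libraries.

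Steap4AKO replicate 2 stood apart from the other libraries. Whether the genotype contributes stays open: of 1171 genes over 2-fold above every Steap4f/f library in Steap4AKO replicate 2, 86 (7.3%) were also so in replicate 3, but 963 of the 1171 were over 2-fold above replicate 3 too, so that this share restates that the pattern was in 1 library. Transcripts of epididymal genes were present in this library, with Akr1b7 at 38528, Crisp1 at 8127 and Serpina1f at 3685. Every other library had at most 3.2, 3.3 and 0 of these. How these transcripts came there stays open, epididymis carried into the sample included. Of 27 listed genes 12 were measured, and only 2 of these reach 11.8, the lowest maximum of any gene in the table, in another library. That all 12 were over 4-fold above every other library was therefore largely fixed by which genes the table holds. Fat of another depot stays open too. Of 8 subcutaneous depot genes, 7 were lowest in this library, from Tbx15 at 0.443% of the lowest other library to Hoxc8 at 66.5%, with Hoxd8 at 159%. Their median was 23.2% of the lowest other library, against 69.6% for the 10 adipocyte markers (26.7 to 681%). At the median these depot genes were therefore reduced further than the adipocyte markers. However, 3 of the depot genes had been seen before the list was written, and the other 5, of which 4 were lowest, are too few to decide. Whether the sample was mislabelled cannot be told apart from how the tissue was taken, because this pattern was in 1 library and a swap with an outside sample needs no partner.

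Of 4 mitochondrial genes with copies on chromosome 1, mt-Co2 (-1.64) and mt-Co3 (-0.11) lay outside the -1.06 to -0.40 of the 9 mitochondrial messenger RNAs without such a copy, and mt-Co1 (-0.88) and mt-Atp6 (-0.81) lay inside it. The larger change of mt-Co2 may come from reads divided with the identical copy Gm28661, since their sum changed by -0.99, within that range, as were the sums of mt-Co1 (-0.90) and mt-Co3 (-1.03) with their copies, while the sum of mt-Atp6 and Gm10925 (-1.11) lay outside it. For Gm29216, which matches mt-Co1 over 483 aligned bases with 1 mismatch, a constant share of mt-Co1 reads is argued against: the lowest Steap4f/f share, 1.05%, would give at least 2823 in a Steap4AKO library, and both were listed at 0. A sequence variant between the mice at that base, in mitochondrial or nuclear DNA, is untested. No biological explanation was tested.

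Of the 15 ways to split the 6 libraries into 4 and 2, the real split called 71 genes and the highest other split 1, so that 1 split gave as many. These splits are too few for a share under 0.05.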
